A study of Homo sapiens with 9 samples.

How the data were processed

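Gene expression was measured in 9 RNA sequencing libraries of the human bronchial epithelial cell line 16HBE14o-, with 1 library for each condition. Per the labels' protocols, cells were treated with 100 µM calpain inhibitor I (ALLN) or with 2.5 µg/ml tunicamycin, and total RNA including its small non-coding fraction was isolated. The libraries cover 2, 4, 6 and 9 h of each compound and 1 control labelled as unstressed, called the control library here. The labels' protocols name a dimethyl sulfoxide control of under 0.5%, and whether the control library received it is not stated.

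The values are FPKM (fragments scaled by transcript length and by mapped fragments) for each gene locus, as deposited by the authors in 1 table. The submitters' processing notes name bcl2fastq 2.18.0.12, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the genome build GRCh37. Whether the authors scaled the FPKM further between libraries, and which annotation they used, is not stated. The table holds 60845 loci, of which 3470 carry no symbol and 2375 carry the joined symbols of several genes. Read totals are not part of it. The most frequent ratio of a treated library's value to that of the control library was taken over loci with 1 transcription start site and values above 0. Of 10510 to 11775 loci compared per library, 783 to 1203 lay within 0.002 log2 units of that ratio. It was read as the ratio of single-fragment values, and so as an estimate of depth relative to the control library. This reading assumes no further scaling between libraries. The absolute depth is unknown, so no counting interval or detection floor was computed.

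Values were transformed to log2(FPKM + 1), a scale that understates the change of genes with low values. Loci without a symbol and 6422 loci with symbols of small RNA classes were left out, as were loci with a mean FPKM under 1 over the 9 libraries. The remaining 14129 loci were tested and are called genes here; 1635 of them carry joined symbols, and 212 symbols occur at several loci. The symbols missed some small RNA, since 112 tested genes are of small RNA classes by annotation, AC005071.1 among them. In 270 tested genes at least 1 library is listed at 0. Of these, 102 are of small RNA classes by annotation. Whether such a 0 is an absence or a failed abundance estimate is not known, so those named are given by library, and a fitted value of such a gene is not a fold.

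Trends were fitted with limma 3.58.1 in R 4.3.3, with 1 prior variance for all genes and Benjamini-Hochberg adjustment over all tested genes at 0.05. The model on all 9 libraries has a common intercept at 0 h and a slope on hours for each compound, which leaves 6 residual degrees of freedom. Estimates are the slope times 9 h, that is, the fitted log2 change over 9 h, and the contrast of the slopes tests whether the trends differ. A second model on the 8 treated libraries gives the mean log2 difference between compounds with the time point as a block, which leaves 3 residual degrees of freedom. Because no condition was replicated, p-values measure only the scatter about the fitted lines or blocks, not the variation between cultures. No single treated library was tested against the control library; genes that differed by 2-fold or more were counted without a test.

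The 29 gene lists cover ER chaperones and folding enzymes, ER-associated degradation, translocation and the early secretory pathway, UPR sensors and transcription factors, the PERK-ATF4 stress response, amino acid synthesis and transport, aminoacyl-tRNA synthetases, proteasome subunits, the cytosolic heat shock response, the NRF2 response, metallothioneins, autophagy and lysosome, immediate early genes, inflammatory and NF-kB target genes, apoptosis regulators, p53 targets, S phase, G2 and M phase, cholesterol synthesis and uptake, N-glycosylation, calpains and cathepsins, candidate substrates of IRE1-dependent decay (RIDD), epithelial junction and keratin genes, mitochondrially encoded mRNAs, ribosomal proteins, replication-dependent histones, and markers of fibroblasts, immune and endothelial cells. The 25 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation, camera on ranks and fry beside it. Adjustment over each list alone was computed as well. Mitochondrially encoded mRNAs, ribosomal proteins and replication-dependent histones, whose mRNAs are non-polyadenylated, were listed as signs of library make-up.

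The lists, the tests, most alternative settings and the rule for named genes were set before the data were examined. By that rule, the 10 genes with the largest positive and the 10 with the largest negative estimate past the threshold are eligible to be named for each trend and for the difference over matched times, though not each eligible gene is printed. They needed a highest FPKM of at least 5 and the same direction at all 4 times, and joined symbols were skipped. Up to 4 members with the largest absolute estimate are eligible from each list, and 8 index genes of the unfolded protein response are given in every comparison: HSPA5, DNAJB9, HERPUD1, XBP1, ATF4, DDIT3, TRIB3 and ATF3.

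Gene coordinates, transcript length and GC content come from a GENCODE annotation on GRCh37, matched by symbol, older symbols included; 11587 tested genes (82%) matched. Each fit was tested on simulated values of 14129 genes with 100 genes changed at each fold size. Simulated trends were linear in hours, and the simulated matched-time difference was the same at all times. The noise was independent and normal, with the residual spread of each gene from the trend fit. The ALLN trend recovered 37 of the 2-fold and 86 of the 4-fold changes, and called 4 unchanged genes. For the tunicamycin trend these were 43, 81 and 6, for the difference of slopes 43, 89 and 3, and for matched times 70, 97 and 10. No changed gene was called in the wrong direction. The matched-time recovery thus holds for a constant difference, not for one that grows over time.

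Alternative settings fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median centring, quantile normalization, small RNA kept, a prior variance that follows expression, time on a log or rank scale, separate intercepts without the control library, each compound fitted alone, no time block, the 6 and 9 h libraries alone, thresholds of 1.5-fold and 4-fold, and each library left out in turn. Chosen after the data were seen were the removal of genes listed at 0, a correction for length and GC content, small RNA left out by annotated class too, an added early component at 2 and 4 h and a mean FPKM of at least 20. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.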

Results

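RNA of 16HBE14o- cells, an immortalised human bronchial epithelial line, was sequenced in 9 libraries with 1 library per condition. The cells had received ALLN, a calpain inhibitor that also blocks the proteasome, or tunicamycin, which blocks N-glycosylation, for 2, 4, 6 or 9 h. The control library stands for 0 h of both compounds, and since no control was sampled at the later times, each trend includes time in culture. The series concerns mRNA changes in the unfolded protein response (UPR), and the comparisons ask which mRNAs moved with each compound and where the compounds differ. The FPKM of a library summed to between 801016 and 1092110. Relative to the control library, sequencing depth was estimated at 0.584 to 0.674 in the ALLN libraries and 0.8 to 1.08 in the tunicamycin libraries. No condition was replicated, so errors are standard errors of the fitted estimates.

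More genes stood 2-fold or more away from the control library at each later time. In ALLN they numbered 440, 778, 1438 and 1851 of 14129 genes at 2, 4, 6 and 9 h, and at 9 h 978 were higher and 873 lower. In tunicamycin they numbered 178, 293, 474 and 603. More were lower than higher there at 2 h (98 and 80) and 4 h (185 and 108), and more were higher at 6 h (324 against 150) and 9 h (400 against 203). These counts describe single libraries and carry no test, and a pseudocount of 0.1, which admits more genes of low value, gave 975 genes for tunicamycin at 9 h. A pseudocount of 5 gave 289 there and 831 for ALLN at 9 h.

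**Figure D1:**
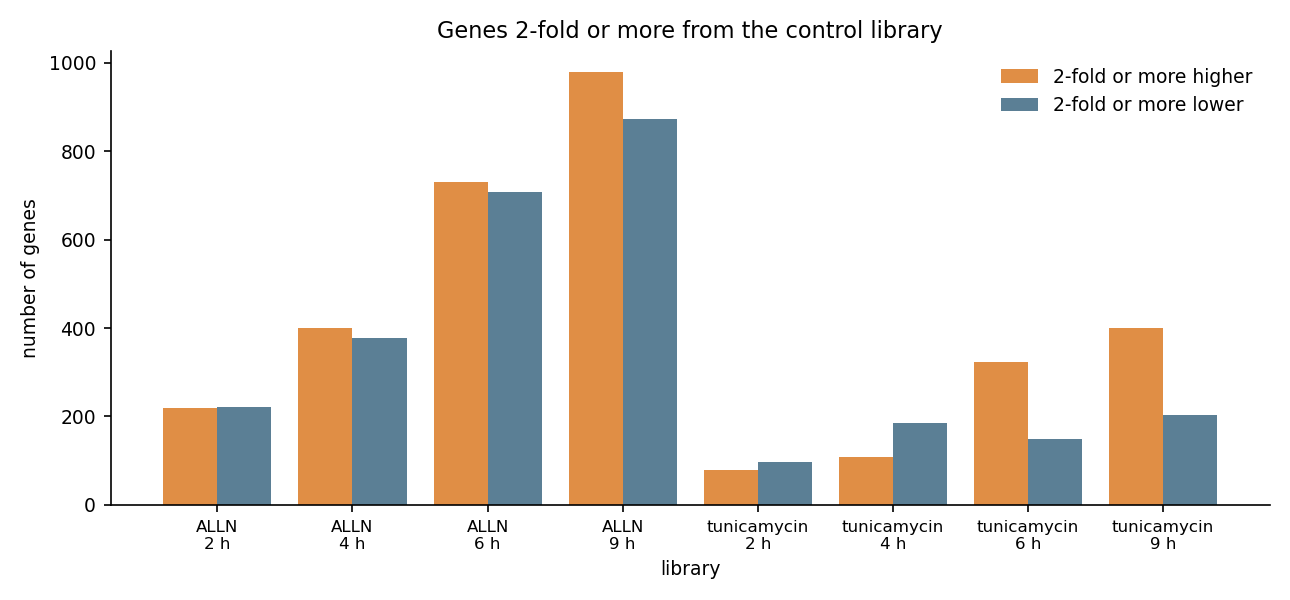
Number of genes, of 14129 tested, that were at least 2-fold higher or lower than the control library in each treated library (y axis) by compound and hours of treatment (x axis), each bar from 1 library. The totals go from 440 to 1851 in ALLN and from 178 to 603 in tunicamycin.

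ALLN was followed by a large increase of cytosolic chaperone mRNAs and by a decrease of mRNAs of proliferation. HSPA6 (locus XLOC_002009, chromosome 1, 161494330 to 161496684, GRCh37), a stress-inducible HSP70, stood at 1.73 FPKM in the control library and at 184, 1290, 1810 and 2320 FPKM after 2, 4, 6 and 9 h of ALLN. Its fitted log2 change over 9 h was 9.32 ± 1.70 (limma, adjusted p = 0.00493). BAG3 (XLOC_006765, chromosome 10, 121410892 to 121437331), a co-chaperone of HSP70, rose from 25.5 to 1310 FPKM, a change of 6.03 ± 0.84 (limma, adjusted p = 0.00156). TOP2A (XLOC_024850, chromosome 17, 38544777 to 38574148), the DNA topoisomerase of dividing cells, fell from 158 to 20 FPKM (-3.01 ± 0.24, limma, adjusted p = 0.000297). EGR1 (XLOC_044584, chromosome 5, 137801168 to 137804992), an immediate early transcription factor, fell from 51.4 to 1.53 FPKM (-5.09 ± 0.72, limma, adjusted p = 0.00161).

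In ALLN, 3811 genes had a trend past the threshold, 1921 rising and 1890 falling, and 920 of the risers and 843 of the fallers changed by 2-fold or more. The other large increases were in MMP3 (7.67 ± 0.73), MMP1 (6.50), KRT33B (7.10 ± 0.66), PRR9 (6.31 ± 0.35), DNAJA4 (6.68 ± 0.56), ZFAND2A (6.60 ± 0.82), the lncRNA RP11-762H8.4 (6.04) and HSPA7 (7.08), a pseudogene whose reads cannot be kept apart from those of HSPA6 with certainty. MMP3 and MMP1 encode secreted matrix metalloproteinases and stood at 321 and 85.5 FPKM after 9 h, against 1.07 and 0.0408 FPKM in the control library. The other large decreases were in H1F0 (-3.19), FBXO5 (-2.85), FAM111A (-2.72), LMNB1 (-2.70 ± 0.22) and CCNE2 (-2.56), which include a linker histone, an inhibitor of the anaphase-promoting complex, a nuclear lamin and a cyclin of S phase entry. Values of 3 further genes with a falling line are listed at 0 in ALLN and give no fold. RPL9P29 stood at 74.7 FPKM in the control library and 16 FPKM at 2 h of ALLN and is listed at 0 at 4, 6 and 9 h. AC005071.1, annotated as a microRNA gene, stood at 12.5 FPKM in the control library and is listed at 0 at all 4 times. RP11-544M22.3 stood at 12.1 FPKM in the control library and at 8.03 and 4.63 FPKM at 2 and 6 h, and is listed at 0 at 4 and 9 h. The count was 2431 without the control library and 1341 with each compound fitted alone. A straight line also fits poorly where an mRNA rose and fell again within 9 h.

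Of 28 tested members of the cytosolic heat shock list, 24 rose, 1 fell and 3 did not pass the test, with a median estimate of 2.74. Adjusted over the list alone, 25 rose and 1 fell. HSPH1, an HSP110 chaperone, rose by 5.72 from 120 to 5170 FPKM, and BAG3 rose with it. The list stood above other genes (limma camera, adjusted p = 3.6e-16; adjusted p = 0.363 with an estimated correlation). HSPA1A had a falling line, which rests on values listed at 0 and gives no fold. It stood at 144 FPKM in the control library and 712 FPKM at 2 h and is listed at 0 at 4, 6 and 9 h of ALLN. Its near-identical copy HSPA1B stood at 32.2 FPKM in the control library and at 326 and 1300 FPKM at 2 and 4 h, and is listed at 0 at 6 and 9 h.

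Of 33 proteasome subunits, 11 rose, 0 fell and 22 did not pass, with a median of 0.57; adjusted over the list alone, 17 rose. With quantile normalization 6 rose and the median was 0.28. PSMD6 rose by 1.29, PSMC4 by 1.11 and PSMD12 by 1.10, all subunits of the regulatory particle (limma camera for the list, adjusted p = 2.01e-07; adjusted p = 0.562 with an estimated correlation). Among 20 NRF2 targets of the oxidative stress response, 10 rose, 1 fell and 9 did not pass, the same counts as adjusted over the list alone. The median was 0.80, or 0.31 with 7 risers and 1 faller under quantile normalization. HMOX1, heme oxygenase, rose by 3.05 from 15.4 to 109 FPKM, FTL, ferritin light chain, by 2.82 from 2030 to 12700 FPKM, and TXNRD1, thioredoxin reductase, by 2.57 (limma camera for the list, adjusted p = 0.000103; adjusted p = 0.512 with an estimated correlation). Of 21 autophagy and lysosome genes, 8 rose, 0 fell and 13 did not pass, and 10 rose adjusted over the list alone. GABARAPL1 rose by 2.19 and MAP1LC3B by 2.02, both of the autophagosome membrane (limma camera for the list, adjusted p = 0.000301; adjusted p = 0.512 with an estimated correlation).

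Of 24 genes of G2 and M phase, 0 rose, 23 fell and 1 did not pass, with a median of -1.49, and 24 fell adjusted over the list alone. AURKB, a mitotic kinase, fell by 2.47 and HMMR by 1.95 (limma camera for the list, adjusted p = 8.82e-16; adjusted p = 0.301 with an estimated correlation). Of 23 genes of S phase and DNA replication, 0 rose, 18 fell and 5 did not pass, with a median of -1.37, and 19 fell adjusted over the list alone. RRM2 and TYMS, enzymes of deoxynucleotide synthesis, fell by 2.19 and by 2.04, and PCNA, the sliding clamp, fell by 1.98 (limma camera for the list, adjusted p = 1.16e-10; adjusted p = 0.363 with an estimated correlation). Of 12 replication-dependent histones, 0 rose and 1 fell, HIST1H2AC (-1.05), and 0 passed adjusted over the list alone (limma, 1 higher and 1 lower at an unadjusted p under 0.05; camera, adjusted p = 0.393).

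Ribosomal protein mRNAs depended on the scaling. With FPKM as deposited, 35 of 66 rose and 0 fell, with a median of 0.66 (limma camera, adjusted p = 6e-12; adjusted p = 0.611 with an estimated correlation), and 46 rose adjusted over the list alone, among them RPL37A (1.17) and RPLP1 (1.14). With quantile normalization their median was -0.016 and 0 passed. The 8 mitochondrially encoded mRNAs had a median of 0.45 as deposited, with 1 riser, MT-ND1 (0.74), also when adjusted over the list alone (limma camera, adjusted p = 0.0349; adjusted p = 0.746 with an estimated correlation). With quantile normalization the median turned to -0.47, 2 fell and MT-ND1 stood at -0.16. All loci with a mitochondrial mRNA symbol, joined symbols included, took 9.81% of all FPKM in the control library and 7.47% to 9.71% in the ALLN libraries. That set is larger than the 8 mRNAs tested.

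The lists of the ER branch of the stress response did not pass as lists in ALLN. Of 23 ER chaperones and folding enzymes, 0 passed in limma, over all genes or adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05. Their median of 0.20 turned to -0.19 with quantile normalization, where 2 fell (limma camera as deposited, adjusted p = 0.511). HSPA5, the ER HSP70 known as BiP, had an estimate of 0.69 (limma, adjusted p = 0.302). In ER-associated degradation, 3 of 23 rose and 1 fell (2 and 1 adjusted over the list alone), among the risers UFD1L (0.79) and VCP (0.76). The median of 0.092 turned to -0.098 with quantile normalization, where 0 rose and 1 fell (limma camera, adjusted p = 0.784). In the translocation and early secretory list, 2 of 30 rose, SEC13 (0.82) and SAR1A (0.82), and 1 did so adjusted over the list alone (limma camera, adjusted p = 0.115). Of 14 UPR sensors and transcription factors, ERN1, which encodes the sensor IRE1, rose by 2.14 and ATF5 fell by 1.13, with the same counts adjusted over the list alone (limma camera, adjusted p = 0.853). Of 30 N-glycosylation genes, 3 rose and 2 fell (1 and 2 adjusted over the list alone), with PGM3 (0.88) among the risers and ALG6 (-1.12) among the fallers. The median of 0.011 turned to -0.068 with quantile normalization, where 0 rose and 2 fell (limma camera, adjusted p = 0.919).

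Apart from amino acid synthesis and transport, the stress signalling lists held risers and fallers in ALLN. Of 25 PERK-ATF4 genes, 5 rose and 3 fell, also when adjusted over the list alone, with RCAN1 (3.46), STC2 (3.01) and PPP1R15A (2.60), a regulator of eIF2α dephosphorylation, among the risers (limma camera, adjusted p = 0.115). Of 20 genes of amino acid synthesis and transport, 4 rose and 0 fell, also when adjusted over the list alone, SLC3A2 and SLC6A9 by 0.85 each (limma camera, adjusted p = 0.0334; adjusted p = 0.809 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases, NARS rose by 0.86 and FARSB and VARS fell by 0.74 and by 0.66, the same counts as adjusted over the list alone (limma camera, adjusted p = 0.288). Of 25 immediate early genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone): IER5 rose by 4.04, the phosphatase gene DUSP1 by 3.28 and MYC by 2.53, while EGR1 fell (limma camera, adjusted p = 0.199). Of 23 inflammatory and NF-kB targets, 4 rose and 5 fell (5 and 6 adjusted over the list alone), with the cytokines IL24 (4.46), IL1B (3.61) and CXCL8 (2.68) among the risers. Their median was -0.27 and the mean 0.34 (limma camera, adjusted p = 0.916).

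The remaining tested lists did not pass camera in ALLN. Of 20 apoptosis regulators, 5 rose and 3 fell, also when adjusted over the list alone: BID rose by 1.28, while BIK and BBC3, which like BID are pro-apoptotic, fell by 1.75 and by 1.48 (limma camera, adjusted p = 0.288). Of 21 p53 targets, 3 rose and 5 fell, also when adjusted over the list alone, DDB2 (-1.63) and POLH (-1.14) among the fallers (limma camera, adjusted p = 0.687). Of 23 cholesterol genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone), with HMGCS1 (1.76) and HSD17B7 (1.17) among the risers (limma camera, adjusted p = 0.288). Of 17 genes in the list of calpains and cathepsins, CTSA (0.78) and CTSL (0.53) rose and CAPN1 fell by 0.62, the same counts as adjusted over the list alone (limma camera, adjusted p = 0.282). With quantile normalization 0 of them rose and 3 fell. Of 8 candidate RIDD substrates, 4 rose and 1 fell, also when adjusted over the list alone, with PMP22 (1.91) and COL6A1 (1.82) among the risers (limma camera, adjusted p = 0.21). Of 25 epithelial junction and keratin genes, 11 rose and 2 fell (11 and 4 adjusted over the list alone), KRT14 by 3.86 and CLDN4 by 1.77 among the risers. Their mean was 0.44 and the median -0.003, which turned to 0.046 with median centring and was -0.27 with quantile normalization, where 8 rose and 4 fell (limma camera, adjusted p = 0.0972). The 4 tested members of the metallothionein list include SLC30A1, not a metallothionein gene. None of the 4 passed in limma, over all genes or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 and MT2A at -1.04. Markers of other cell types were low in all libraries. Of the fibroblast markers 3 reached a mean FPKM of 1, and 1 of them, COL1A1, rose from 4.86 to 16.6 FPKM in ALLN (1.69). Of the immune markers 1 did, CSF1R, which rose from 1.73 to 4.91 FPKM (1.03). Of the endothelial markers 1 did, KDR, with an estimate of 0.27 (limma, adjusted p = 0.399). Adjusted over each list alone, these counts were the same.

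Tunicamycin was followed by an increase of ER folding and secretory mRNAs. BHLHA15 (XLOC_050576, chromosome 7, 97840751 to 97844769), a transcription factor of secretory cells also known as MIST1, rose from 1.60 FPKM to 2.03, 8.89, 37.9 and 40.9 FPKM (4.55 ± 0.50, limma, adjusted p = 0.00611). HSPA5 (XLOC_057504, chromosome 9, 127997132 to 128003661) rose from 174 FPKM to 213, 736, 1360 and 2360 FPKM (3.68 ± 0.47, limma, adjusted p = 0.00928). DNAJB9, an ER co-chaperone of HSPA5, rose from 20.4 to 230 FPKM (3.61 ± 0.59, limma, adjusted p = 0.0196). CDSN (XLOC_048561, chromosome 6, 31082864 to 31088223), corneodesmosin, an adhesion protein of stratified epithelium, fell from 99.2 FPKM to 84.2, 42.7, 18.9 and 10.2 FPKM (-3.44 ± 0.24, limma, adjusted p = 0.0012).

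In tunicamycin, 266 genes had a trend past the threshold, 206 rising and 60 falling, and 178 and 35 of them changed by 2-fold or more. SDF2L1 (3.23 ± 0.34), CRELD2 (3.08 ± 0.30), DERL3 (2.99), FICD (2.74) and SEL1L (2.51), all of ER folding or degradation, were also among the largest increases, as was KRT33B (3.62). The lncRNA GHET1 is listed at 0 in the control library and all ALLN libraries and stood at 2.2, 7.15, 2.31 and 19.5 FPKM in tunicamycin. BCAM, a laminin receptor, fell by 2.54 from 95.5 to 17.2 FPKM, and the next largest decreases were in TNS4 (-1.90), SEMA7A (-1.56), TGOLN2 (-1.48), C4orf26 (-1.39), LYPD3 (-1.34), MLLT11 (-1.31), ADAM19 (-1.28) and MGAT4B (-1.25), the last an N-glycan branching enzyme. The count rests on few libraries: it was 1 (limma, 1049 at an unadjusted p under 0.05) without the 9 h tunicamycin library, 93 without the 6 h and 121 without the 2 h tunicamycin library, 113 without the control library and 143 without the 2 h ALLN library. It was 0 with tunicamycin fitted alone (limma, 2494 at an unadjusted p under 0.05) and 1 with time on a log scale (limma, 1423 at an unadjusted p under 0.05). The estimates of HSPA5 were 4.12 and 3.61 in these fits and those of CDSN -3.44 and -3.09.

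Of 23 ER chaperones and folding enzymes, 18 rose, 0 fell and 5 did not pass in tunicamycin, with a median of 1.99, and 22 rose adjusted over the list alone. ERO1B, an ER oxidase, rose by 3.18 (limma camera for the list, adjusted p = 1.82e-33; adjusted p = 0.0685 with an estimated correlation). In the translocation and early secretory list, 8 of 30 rose, 0 fell and 22 did not pass, with 21 risers adjusted over the list alone. SEC23B (1.5), of the COPII coat, SEC61A1 (1.45), of the translocon, and SSR3 (1.40) were among them (limma camera, adjusted p = 1.98e-19; adjusted p = 0.0685 with an estimated correlation). In ER-associated degradation, 6 of 23 rose, 0 fell and 17 did not pass, with 11 risers adjusted over the list alone, among them DERL3, SEL1L and VIMP (1.98) (limma camera, adjusted p = 1.92e-08; adjusted p = 0.129 with an estimated correlation). Of 30 N-glycosylation genes, 6 rose, 0 fell and 24 did not pass, with 14 risers and 1 faller adjusted over the list alone, and GFPT1 (1.94), OSTC (1.86) and PGM3 (1.59) rose (limma camera, adjusted p = 6.78e-08; adjusted p = 0.0685 with an estimated correlation). Of 14 UPR sensors and transcription factors, EIF2AK3, which encodes the sensor PERK, rose by 2.31 and CREB3L2 by 2.09, with 5 risers adjusted over the list alone (limma camera, adjusted p = 0.000264; adjusted p = 0.222 with an estimated correlation).

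Camera called 6 further lists in tunicamycin, with few single genes past the threshold. Of 25 PERK-ATF4 genes, RCAN1 rose (1.89), and 4 rose adjusted over the list alone (limma camera, adjusted p = 0.00539; adjusted p = 0.635 with an estimated correlation). Of 20 genes of amino acid synthesis and transport, ALDH1L2 rose (1.68), and of 19 aminoacyl-tRNA synthetases AARS rose (1.23), with 2 risers adjusted over the list alone in both (limma camera, adjusted p = 0.00385 and 0.000585; adjusted p = 0.635 and 0.633 with an estimated correlation). Of 12 replication-dependent histones, HIST2H2BF rose (1.23), the list median was 0.85 and 6 rose adjusted over the list alone (limma camera, adjusted p = 1.97e-07; adjusted p = 0.0685 with an estimated correlation). Of 17 calpains and cathepsins, 0 passed in limma over all genes (0 higher and 3 lower at an unadjusted p under 0.05) and 1 fell adjusted over the list alone. The list median was -0.28, with 5 of 17 estimates positive (limma camera, adjusted p = 0.00637; adjusted p = 0.222 with an estimated correlation). In the epithelial list, SCNN1A, a subunit of the epithelial sodium channel, fell by 1.06, 24 of 25 did not pass and 2 fell adjusted over the list alone (limma camera, adjusted p = 0.00751; adjusted p = 0.493 with an estimated correlation).

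The other lists gave no camera call in tunicamycin. The heat shock list had a median of -0.21, with 0 of 28 past the threshold in limma (0 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.162). Its median log2 differences from the control library were 0.04, -0.043, -0.132 and 0.105 at 2, 4, 6 and 9 h. The fitted median, which uses the intercept shared with ALLN, is thus not a fall from the control library. The proteasome list had a median of -0.11, with 0 of 33 (0 at an unadjusted p under 0.05; camera, adjusted p = 0.128). The replication licensing factor CDC6 rose from 122 to 449 FPKM as the 1 riser among 23 S phase genes, also adjusted over the list alone. The S phase median was 0.023, which turned to -0.02 with quantile normalization (limma camera, adjusted p = 0.424). Of 24 G2 and M phase genes, 0 passed in limma (0 at an unadjusted p under 0.05), with a median of -0.081 (camera, adjusted p = 0.543). In the autophagy list WIPI1 rose by 2.25 and ATG13 by 0.95, also adjusted over the list alone (limma camera, adjusted p = 0.0804). In the cholesterol list HSD17B7 rose by 0.96, with 1 riser and 2 fallers adjusted over the list alone (limma camera, adjusted p = 0.0783). The limma counts were 0 for NRF2 targets, immediate early genes, inflammatory genes, apoptosis regulators, p53 targets, RIDD candidates, mitochondrial mRNAs, ribosomal proteins, metallothioneins and the markers of fibroblasts, immune and endothelial cells. Adjusted over each list alone they were 0 as well, save 1 riser among the RIDD candidates. At an unadjusted p under 0.05 the higher and lower genes were 2 and 1 for inflammatory genes, 1 and 2 for apoptosis regulators and 1 and 2 for RIDD candidates. They were 0 and 1 for immediate early genes and mitochondrial mRNAs, and 0 and 0 for the others. Camera gave adjusted p = 0.128 for NRF2 targets and immediate early genes, 0.758 for inflammatory genes, 0.658 for apoptosis regulators, 0.359 for p53 targets, 0.21 for RIDD candidates, 0.0783 for mitochondrial mRNAs and 0.319 for ribosomal proteins. COL1A1 stood at 0.45 and CSF1R at -0.12 (limma, adjusted p = 0.46 and 0.925).

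**Figure D2:**
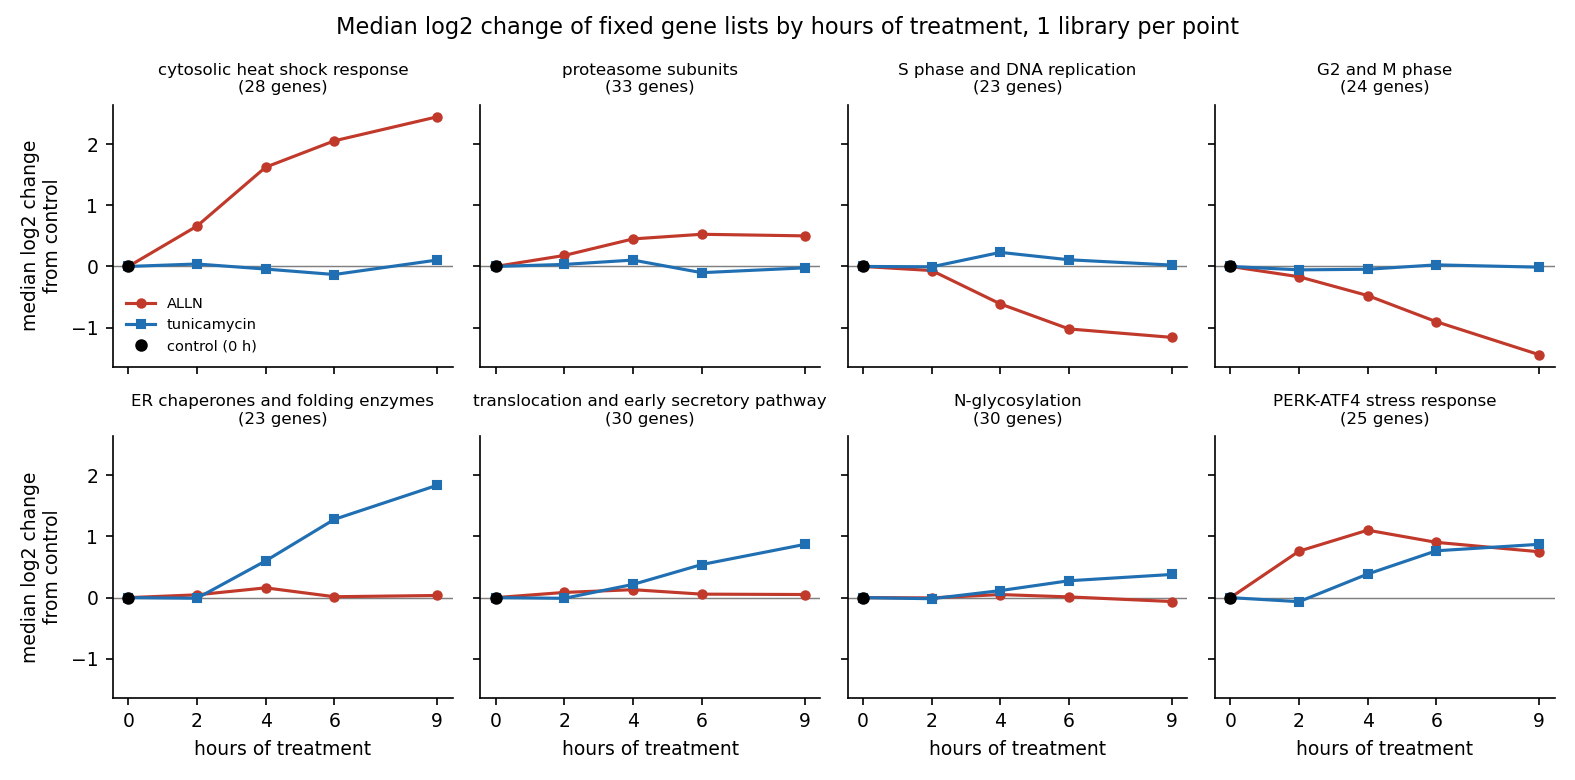
Median log2 difference from the control library over the members of selected gene lists (y axis) by hours of treatment (x axis) for ALLN and for tunicamycin, with each point from 1 library. The heat shock median reaches 2.45 at 9 h of ALLN and 0.11 at 9 h of tunicamycin, and the ER chaperone median 0.035 and 1.84.

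The compounds were then compared directly by the difference of their slopes, ALLN minus tunicamycin. HSPA5 (-2.99, limma, adjusted p = 0.00118), DNAJB9 (-3.83, limma, adjusted p = 0.0011), HERPUD1 (-3.45, limma, adjusted p = 0.00938) and DDIT3 (-2.34, limma, adjusted p = 0.0171) had lower slopes in ALLN. HERPUD1 acts in ER-associated degradation, and DDIT3 encodes the transcription factor CHOP. HSPA6 (11.22), DNAJA4 (7.07), MMP3 (6.89) and BAG3 (6.82) had higher slopes in ALLN. For HSPA6 and BAG3 the difference exceeds the ALLN trend itself, because the early jump in ALLN raises the shared intercept and lowers the fitted tunicamycin line. In all, 4736 genes differed, 2215 with the higher slope in ALLN and 2521 with the lower, and the count was 2084 without the 9 h tunicamycin library. It was 938 with separate intercepts and no control library. Of the 206 genes that rose in tunicamycin, 167 had a slope that differed from that in ALLN, as did 41 of its 60 fallers and 2904 of the 3811 trend genes of ALLN.

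**Figure D3:**
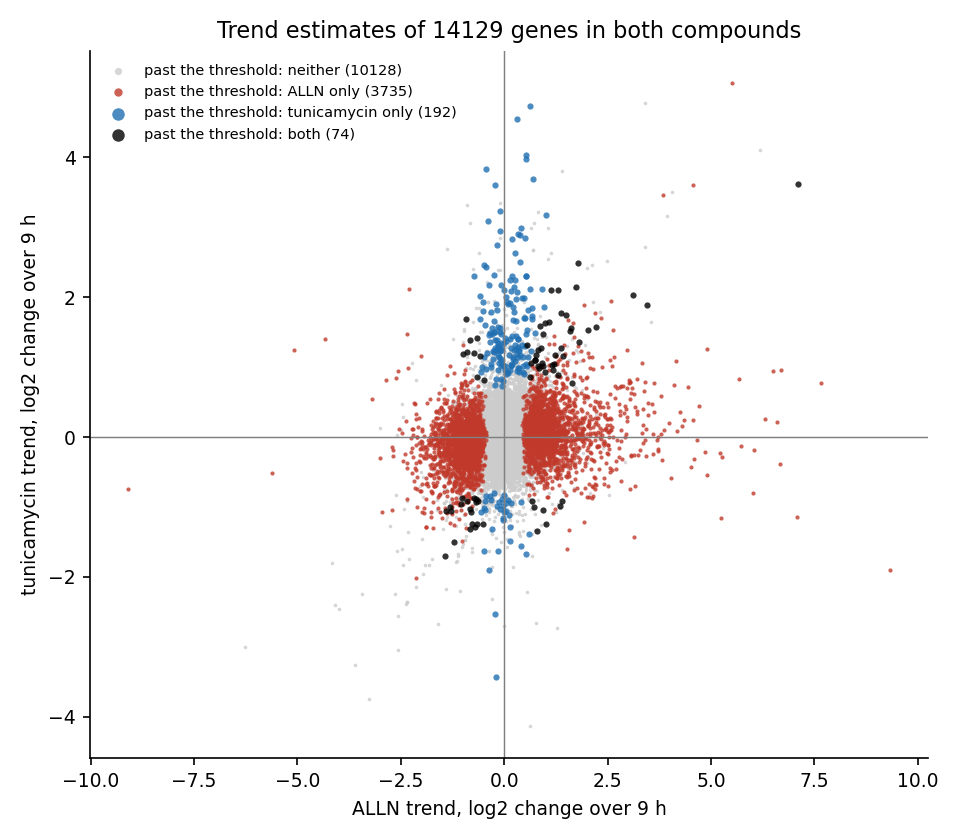
Fitted log2 change over 9 h in ALLN (x axis) against that in tunicamycin (y axis) for each of 14129 genes, coloured by which trend passed the threshold. Of these genes, 3735 passed in ALLN alone, 192 in tunicamycin alone and 74 in both.

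By list, 21 of 23 ER chaperones had the lower slope in ALLN, with a median difference of -1.61 (limma camera, adjusted p = 1.04e-11; adjusted p = 0.227 with an estimated correlation). So had 14 of 30 translocation and secretory genes (limma camera, adjusted p = 0.000129; adjusted p = 0.302 with an estimated correlation). In ER-associated degradation 11 of 23 were lower and 1 higher, in N-glycosylation 13 of 30 and 1, and among UPR sensors and transcription factors 7 of 14 and 1 (limma camera, adjusted p = 0.00288, 0.000879 and 0.0136; adjusted p = 0.302, 0.227 and 0.302 with an estimated correlation). All 24 G2 and M phase genes, 19 of 23 S phase genes and 8 of 12 histones had the lower slope in ALLN (limma camera, adjusted p = 7.89e-14, 6.47e-11 and 0.000475, and 0.227 with an estimated correlation for each). Histone mRNAs of this list are non-polyadenylated, and the library kit is not stated. A difference in library make-up thus cannot be told apart from a change in the cells for them. The histone list, with 12 of 66 members tested, had a median of 0.85 in tunicamycin. In ALLN its median was -0.25 and it did not pass (limma camera, adjusted p = 0.393). Higher slopes in ALLN were found for 24 of 28 heat shock genes, with 1 lower, 20 of 33 proteasome subunits and 14 of 20 NRF2 targets, with 1 lower (limma camera, adjusted p = 6.59e-16, 1.11e-08 and 1.37e-05; adjusted p = 0.227, 0.281 and 0.248 with an estimated correlation). They were also found for 12 of 25 epithelial genes, with 1 lower, 9 of 21 autophagy genes, with 2 lower, and 5 of 17 calpains and cathepsins (limma camera, adjusted p = 0.0015, 0.017 and 0.00821; adjusted p = 0.277, 0.335 and 0.248 with an estimated correlation). Among immediate early genes 8 of 25 were higher and 4 lower, and among cholesterol genes 6 of 23 and 1 (limma camera, adjusted p = 0.0257 and 0.0419; adjusted p = 0.531 with an estimated correlation for both). The higher slopes of 29 of 66 ribosomal proteins and 5 of 8 mitochondrial mRNAs (limma camera, adjusted p = 1.78e-10 and 0.0017; adjusted p = 0.335 and 0.302 with an estimated correlation) depended on the scaling. With quantile normalization 0 were higher in either list, and the medians were 0.024 and -0.18. The epithelial list then had a median of 0.016, with 8 higher and 2 lower. The PERK-ATF4 list, with 6 of 25 higher and 5 lower, did not differ in slope as a list, and its median of 0.22 turned to -0.043 with quantile normalization (limma camera, adjusted p = 0.85). Adjusted over the list alone, 6 were higher and 9 lower. A slope reflects little of a difference already reached at 2 h. There the PERK-ATF4 median log2 difference from the control library was 0.76 in ALLN and -0.066 in tunicamycin. Adjusted over the list alone, the lower slope in ALLN was found for 21 ER chaperones, 16 translocation and secretory genes, 12 of ER-associated degradation, 13 of N-glycosylation, 9 UPR sensors and transcription factors, 24 G2 and M phase genes, 20 S phase genes and 10 histones. Members with the higher slope in these lists were 1 each in translocation, ER-associated degradation and N-glycosylation and 2 UPR sensors and transcription factors. The higher slope was found for 24 heat shock genes, 23 proteasome subunits, 14 NRF2 targets, 12 epithelial genes, 9 autophagy genes, 5 calpains and cathepsins, 9 immediate early genes, 6 cholesterol genes, 40 ribosomal proteins and 7 mitochondrial mRNAs. Members with the lower slope in these lists were 2 heat shock, 1 NRF2, 1 epithelial, 3 autophagy, 4 immediate early and 1 cholesterol gene.

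Of the 8 index genes of the UPR, 4 had slopes shown to differ between the compounds, HSPA5, DNAJB9, HERPUD1 and DDIT3. HERPUD1 stood at 146 FPKM in the control library, at 607, 522, 274 and 249 FPKM in ALLN and at 369, 2010, 2040 and 2300 FPKM in tunicamycin. XBP1, the target of IRE1 splicing, stood at 92.4 FPKM in the control library, at 198, 165, 98.2 and 73.9 FPKM in ALLN and at 93.4, 161, 151 and 161 FPKM in tunicamycin. ATF3 went from 16.8 FPKM to 91.6, 71.2, 37.4 and 21.1 FPKM in ALLN and to 19.5, 35.0, 49.4 and 45.6 FPKM in tunicamycin. DDIT3 went from 26.3 FPKM to 76.1, 61.3, 51.6 and 73.1 FPKM in ALLN and to 54.7, 260, 219 and 252 FPKM in tunicamycin. TRIB3, a target of ATF4 and CHOP, went from 68.5 FPKM to 113, 124, 88.8 and 76.7 FPKM in ALLN and to 61.4, 106, 155 and 170 FPKM in tunicamycin. ATF4 stood between 255 and 409 FPKM in all treated libraries, against 315 FPKM in the control library. In ALLN 0 of the 8 index genes passed the linear test in limma, with adjusted p between 0.302 (HSPA5) and 0.942 (ATF3). HERPUD1 had an estimate of -0.10 (limma, adjusted p = 0.939), which turned to 0.96 with time on a log scale. ATF3 had one of 0.10 (limma, adjusted p = 0.942), which turned to -0.40 with ALLN fitted alone. With separate intercepts and no control library, ATF3 fell by 2.78 (limma, adjusted p = 0.0133). In tunicamycin HERPUD1 (3.35, limma, adjusted p = 0.0885) and DDIT3 (2.98, limma, adjusted p = 0.0558) fell short of the threshold that HSPA5 and DNAJB9 passed. With small RNA left out by annotated class too, DDIT3 passed (limma, adjusted p = 0.0447). The slopes of XBP1 (-0.75), ATF4 (-0.53), TRIB3 (-0.82) and ATF3 (-0.24) were not shown to differ (limma, adjusted p = 0.226, 0.0522, 0.127 and 0.843).

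**Figure D4:**
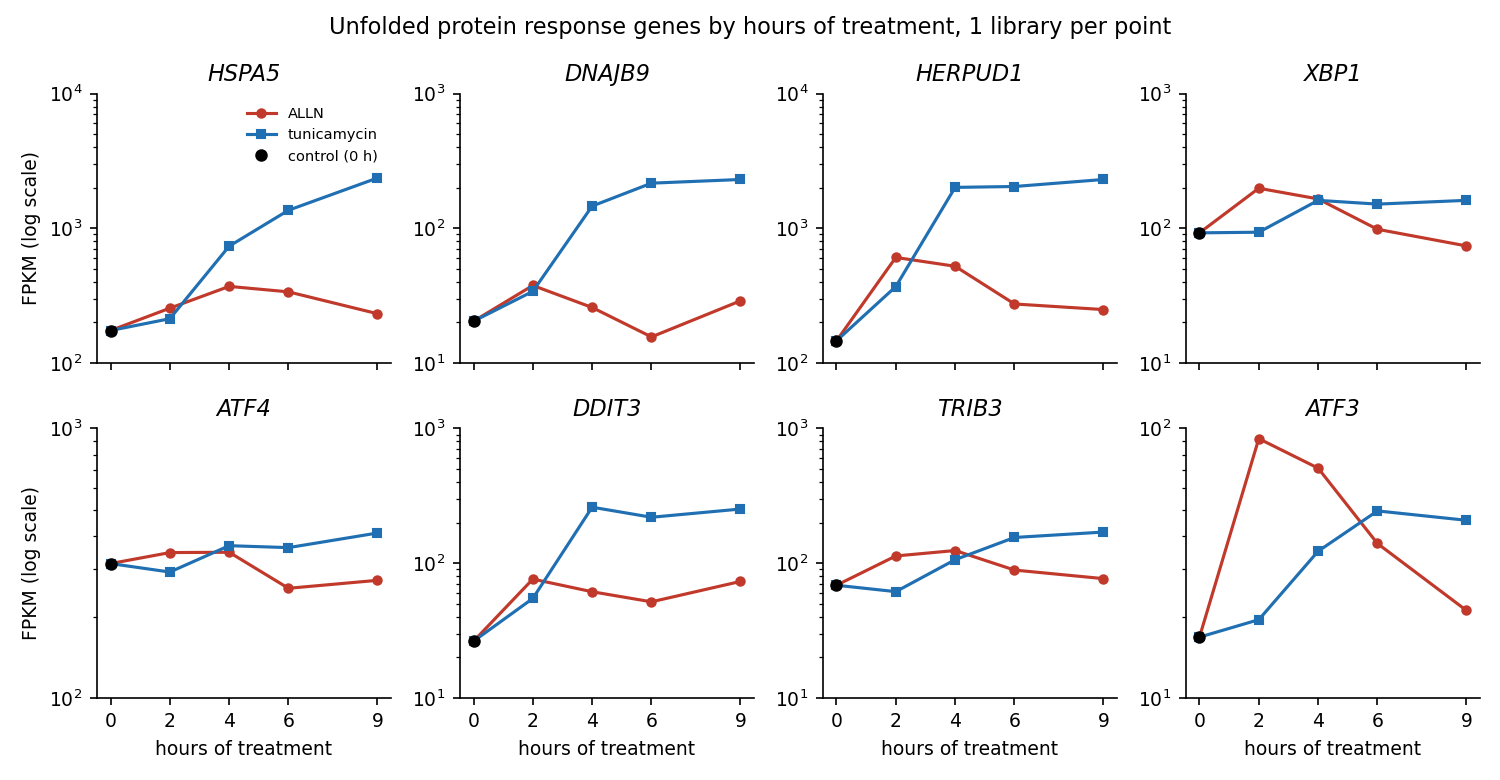
FPKM on a log axis (y axis) of the 8 index genes of the UPR by hours of treatment (x axis) in ALLN and in tunicamycin, with the control library as 0 h and each point from 1 library. HSPA5 reaches 2360 FPKM after 9 h of tunicamycin and 232 FPKM after 9 h of ALLN.

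Averaged over the 4 matched times, and so without the control library, some heat shock and signalling genes stood higher in ALLN. HSPA6 (7.39 ± 0.86, limma, adjusted p = 0.0433), BAG3 (4.43) and DNAJB1 (4.28 ± 0.40, limma, adjusted p = 0.0388), an HSP40, showed the largest differences. DNAJB1 stood at 776, 2900, 3250 and 3510 FPKM in ALLN and at 121, 115, 110 and 115 FPKM in tunicamycin. IL1B, a cytokine (2.73 ± 0.14, limma, adjusted p = 0.013), DUSP1 (2.43 ± 0.14), the connective tissue growth factor gene CTGF (2.2), EID3 (2.21), THBD (2.09) and SOX9 (2.07) were also higher in ALLN. EGR1 was lower in ALLN (-4.15 ± 0.50, limma, adjusted p = 0.0433), as were ZNF367 (-1.70), FJX1 (-1.48), SLC2A10 (-1.30), RMI2 (-1.26), NECTIN4 (-1.21), PITPNA-AS1 (-1.11) and CETN3 (-1.02). AC005071.1 is listed at 0 in all ALLN libraries and stood at 29.3, 31.8, 15.4 and 11.8 FPKM in tunicamycin. RP5-1021I20.8 stood at 1.88, 4.08, 7.89 and 3.03 FPKM in tunicamycin and at 2.80 FPKM at 6 h of ALLN, and is listed at 0 at 2, 4 and 9 h of ALLN.

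In all, 89 genes differed over the matched times, 70 higher and 19 lower in ALLN. With median centring 194 differed, 65.5% of them higher against 78.7% as deposited, and 290 with the correction for length and GC content, 63.8% of them higher. With small RNA left out by annotated class too, 360 differed, 62.8% of them higher. The excess of higher genes depends on the fit: 535 were higher and 538 lower with no time block, and 1254 and 1521 with 6 and 9 h alone. The count depends on which times enter: it was 1387 without either of the 2 h libraries (665 higher and 722 lower), and 0 without any 1 of the 4, 6 or 9 h libraries of either compound. At an unadjusted p under 0.05 limma gave 2669, 2000 and 3011 genes without a 4, a 6 and a 9 h library. By list, 24 of 28 heat shock genes were higher and 1 lower adjusted over the list alone, and 4 higher over all genes (limma camera, adjusted p = 3.77e-12; adjusted p = 0.623 with an estimated correlation). Of 25 immediate early genes, 4 were higher, 1 was lower and 20 did not pass, with 9 higher and 3 lower adjusted over the list alone (limma camera, adjusted p = 0.000442; adjusted p = 0.623 with an estimated correlation). Adjusted over the list alone, 11 of 33 proteasome subunits and 13 of 20 NRF2 targets were higher, and 11 of 23 ER chaperones, 15 of 23 S phase genes and 15 of 24 G2 and M phase genes lower. Over all genes 0 of each of these lists passed in limma (19, 14, 15, 18 and 19 at an unadjusted p under 0.05). Of 25 PERK-ATF4 genes, 2 were higher and 0 lower over all genes, and 9 higher and 2 lower adjusted over the list alone. The list median was 0.434, and the list did not pass (limma camera, adjusted p = 0.0529, and 0.634 with an estimated correlation). Of the 25 lists, 17 were called by camera, 18 by camera on ranks, 4 by fry and 0 with an estimated correlation (1 at an unadjusted p under 0.05).

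Trends with both compounds were found for 74 genes. Of these, 39 rose with both compounds, against 28 for independent lists, and 19 fell with both, against 8.03; 7 rose in ALLN and fell in tunicamycin, against 8.16, and 9 did the reverse, against 27.6. Across genes, which are not independent replicates, the estimates correlated at 0.219 with a covariance of 0.084, while 100 simulations with no effect and the shared control library gave 0.556 and 0.075. The covariance was near that with no effect, so much or all of the excess overlap may come from the 1 shared control library, which cannot be divided. Without the control library and with separate intercepts the correlation was -0.062.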

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

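The tests of depth, of length and GC content, of values listed at 0 and of the early response were chosen after the results were seen, while the counts over other orders and splits of the libraries were planned. The results below stand out because the trends in ALLN and tunicamycin differ by the test of the difference of slopes (limma, Benjamini-Hochberg). No condition has replicates, so no library was compared with others of its group.

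In all, 4736 genes had slopes that differ. Of 35 splits of the 8 treated libraries, 1, the real one, gave as many (highest other 4193, from exchanging the 2 h libraries alone), but most splits set unequal times against each other. The splits with 1 library of each time in each arm number 8, too few for a share under 0.05. For the ALLN trend 1 of 100 orders, the real one, gave as many as 3811 genes (highest other 3243). The order with 3243 genes exchanges the control and the 2 h library, and 91 of the 99 orders drawn besides the real one gave 0 genes. The share thus shows a course that is smooth in this order and little more. For the tunicamycin trend 2 of 100 orders gave at least 266 genes, the real one included, and 89 of the 99 others gave 0, with the same limit. The order with 325 genes also exchanges the control and the 2 h library. Reordering libraries of 1 series tests neither variation between cultures nor a drift with time in culture. For matched times chance is not excluded: 3 of 32 splits gave at least 89 genes, and the highest other is 2008. The splits with 2008 genes keep the compounds apart at 6 and 9 h, while their 2 and 4 h pairs carry no contrast beside the time block. They thus hold the real difference at 6 and 9 h, where 2775 genes differed with these times alone. Among the 8 splits with matched times the highest other is 0. Leaving out 1 library moved these counts: slopes to 2084 without 9 h of tunicamycin, the ALLN trend to 2431 without the control, and the tunicamycin trend to 1 without its 9 h library, 93 without 6 h, 121 without 2 h, 113 without the control and 143 without 2 h of ALLN. The matched-time count went to 0 without any 1 library of 4, 6 or 9 h (limma, 2669, 2000 and 3011 at an unadjusted p under 0.05) and to 1387 without either 2 h library.

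Lists with the lower slope in ALLN, by median difference, were ER chaperones (-1.61), S phase (-1.37), G2 and M phase (-1.35), histones (-1.07), UPR sensors and transcription factors (-0.85), N-glycosylation (-0.61), ER-associated degradation (-0.60) and translocation and early secretory genes (-0.60). Lists with the higher slope were heat shock (2.94), NRF2 targets (0.82), mitochondrial mRNAs (0.68, turned to -0.18 by quantile normalization), proteasome subunits (0.63), autophagy (0.58), immediate early genes (0.58), ribosomal proteins (0.58, 0.024 with quantile normalization), epithelial genes (0.55, 0.016 with quantile normalization), calpains and cathepsins (0.39) and cholesterol genes (0.21). These 18 lists were called by camera in limma, and with an estimated correlation 0 of them were (adjusted p = 0.227 to 0.531; 5 at an unadjusted p under 0.05). Of the 174 genes named from lists for a trend, 115 had slopes that differ, against 4736 of 14129 over all genes. These genes and those below were chosen for large estimates, which itself favours slopes that differ, so the share is no test.

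Among the index genes, the difference of slopes was -2.99 for HSPA5, -3.83 for DNAJB9, -3.45 for HERPUD1 and -2.34 for DDIT3. Among the largest ALLN risers it was 11.22 for HSPA6, 8.22 for HSPA7, 7.07 for DNAJA4, 6.89 for MMP3, 6.82 for BAG3, 6.38 for ZFAND2A, 6.23 for RP11-762H8.4, 6.06 for PRR9, 5.56 for MMP1 and 3.48 for KRT33B. Among the largest ALLN fallers it was -6.32 for EGR1, -3.73 for H1F0, -3.67 for FBXO5, -3.51 for CCNE2, -2.71 for TOP2A, -2.57 for FAM111A and -2.52 for LMNB1. Among the largest tunicamycin risers it was -4.24 for BHLHA15, -3.48 for CRELD2, -3.33 for SDF2L1, -2.91 for FICD, -2.58 for DERL3 and -2.12 for SEL1L. Among the tunicamycin fallers it was 3.25 for CDSN, 2.32 for BCAM, 2.14 for LYPD3, 1.99 for C4orf26, 1.97 for SEMA7A, 1.63 for TGOLN2, 1.54 for TNS4, 1.44 for ADAM19, 1.02 for MLLT11 and 0.73 for MGAT4B. The fitted values of 3 genes rest on values listed at 0 and are not folds: -5.73 for AC005071.1 (at 0 in all 4 ALLN libraries), -5.09 for RPL9P29 (at 0 in 3 ALLN libraries) and -4.27 for GHET1 (at 0 in the control and all 4 ALLN libraries).

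More genes had a trend in ALLN (3811, or 2431 without the control library) than in tunicamycin (266, or 1, 93, 121, 113 and 143 without the 9, 6 or 2 h tunicamycin, the control or the 2 h ALLN library). A lower depth of the ALLN libraries is argued against as the source, because the spread of the 9 h log2 changes in ALLN was 1.876 times that in tunicamycin among genes with a mean FPKM of at least 100, where depth matters least. Transcript length and GC content accounted for 0.329% of the variance of the ALLN estimates, which argues against such a bias. A stronger or more sustained response to this dose of ALLN stays open, as does the choice of doses, whose relative strength is not known. Time in culture was shared by both compounds and could add to either trend, since no control was sampled at the later times.

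HSPA1A is listed at 0 in 3 ALLN libraries and HSPA1B in 2, while both stood above the control library at 2 h. In the libraries with HSPA1A at 0, the other 26 tested heat shock genes had a median log2 change of 2.287 and 0 of them were listed at 0. A candidate explanation is a failed abundance estimate for this pair of near-identical copies in the deposited table, and of the 5601 loci with at least 20 FPKM in the control library and outside the small RNA classes, 3 are listed at 0 in a library, the pair and RPL9P29. The data hold no reads to test this further, and a biological loss of these mRNAs was not tested.

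The UPR genes HERPUD1, XBP1 and ATF3 were highest at 2 h of ALLN. With an early component added at 2 and 4 h, 21 of 25 PERK-ATF4 genes had a positive one, with a median of 0.65 (limma camera, adjusted p = 2.7e-07; adjusted p = 0.58 with an estimated correlation). It was not shown for ER chaperones, ER-associated degradation or translocation (limma camera, adjusted p = 0.151, 0.381 and 0.167). A positive component was not confined to the UPR. It was found for 22 of 24 G2 and M phase, 22 of 23 cholesterol and 22 of 25 immediate early genes. The component measures a departure from the fitted line, not a rise from the control library. The G2 and M phase list lay below the control library throughout ALLN, with medians of -0.169, -0.476, -0.904 and -1.444 in time order. An early component does not show a transient response, since a rise that comes early and is held also gives a positive one. The PERK-ATF4 list was still raised at 9 h of ALLN. Its median log2 differences from the control library were 0.76, 1.103, 0.904 and 0.75 at 2, 4, 6 and 9 h. The camera call also ends with an estimated correlation, and 0 single genes passed for this component in limma (1322 at an unadjusted p under 0.05). With 1 library per time, an early component cannot be told apart from correlated noise. The 2 h library as the sole source is argued against, because the median early component of the PERK-ATF4 list without it was 83.4% of that with all libraries.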

How the results depend on the processing

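The removal of genes listed at 0, the correction for length and GC content, the removal of small RNA by annotated class, the early component and the FPKM minimum of 20 were tried after the results were seen. No analysis paired by replicate number was possible because the conditions share only 1 replicate number. The matched-time comparison instead pairs the compounds by time point, used as its block. Where values moved, the cause was not tested unless the setting itself changes the genes or libraries used. Depth limits low genes most, and it is estimated only relative to the control library.

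With quantile normalization, of 100 genes named for the ALLN trend 84 stayed as called, 14 weakened, 1 strengthened and 1 reversed, MT-ND1 (-0.157), while all 46 named for tunicamycin stayed. With median centring 99 of 100 and 45 of 46 stayed. Far fewer of both sets stayed with each compound fitted alone (55 and 6) and with separate intercepts (53 and 19). With separate intercepts 5 of the ALLN genes reversed. With log time 83 and 7 stayed, and without the 9 h tunicamycin library 85 and 7. There far fewer stayed among the tunicamycin genes only, since the ALLN numbers were near the 84 with quantile normalization. Of 32 genes named for matched times, 6 to 8 stayed without a 4, 6 or 9 h library, 8 with no filter and 12 with a pseudocount of 0.1 or with small RNA kept.

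The ALLN count was 2472 with time on a log scale, 1909 with separate intercepts and no control library, 1341 with the compound fitted alone and 1857 at an FPKM of at least 20, where fewer genes are tested. Leaving out 1 library gave 2431 (control) to 3704 (4 h ALLN). The tunicamycin count was 123 with no filter, 1 with log time, 82 with separate intercepts, 0 when fitted alone (limma, 2494 at an unadjusted p under 0.05) and 118 with the early component. Leaving out 1 library gave 1 (9 h tunicamycin) to 297 (9 h ALLN), and 113, 143, 121 and 93 without the control, 2 h ALLN, 2 h tunicamycin and 6 h tunicamycin libraries. The difference of slopes gave 938 genes with separate intercepts, 2148 at an FPKM of at least 20, and 2084 (without 9 h tunicamycin) to 4746 (without 2 h ALLN).

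The matched-time count was 12 with a pseudocount of 0.1, 0 with no filter (limma, 5891 at an unadjusted p under 0.05), 466 at an FPKM of at least 5, 205 at 20, 194 with median centring, 11 with small RNA kept, 360 with small RNA left out by annotated class too, 264 with a prior variance that follows expression, 1073 with no time block, 2775 with 6 and 9 h alone, 608 without genes listed at 0 and 290 with length and GC content corrected. Leaving out 1 library gave 0 to 1387.

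In ALLN, HERPUD1 turned to 0.957 with log time, 0.079 with ranked time, 0.082 when fitted alone and 0.705 with the early component, and DNAJB9 to 0.381 with log time and 0.117 with the early component. With separate intercepts, HSPA5 was -0.297, DDIT3 -0.084, TRIB3 -0.839, ATF3 -2.78 and AC005071.1 0, since it is listed at 0 in all ALLN libraries; fitted alone, TRIB3 was -0.056 and ATF3 -0.396. Leaving out 1 library gave ALLN ranges of -0.89 to 0.118 for DNAJB9, -1.171 to 0.649 for HERPUD1, -0.919 to 0.28 for XBP1, -0.057 to 0.97 for DDIT3, -0.014 to 0.992 for TRIB3 and -0.769 to 1.863 for ATF3, and tunicamycin ranges of -0.17 to 0.601 for XBP1 and -0.528 to 0.998 for ATF3. Over matched times the ranges were -0.562 to 0.166 for XBP1, -0.572 to 0.097 for TRIB3 and -0.155 to 0.93 for ATF3, which was -0.735 at 6 and 9 h alone. None of these index genes passed in the comparison concerned with the deposited values.

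The 2-fold counts in time order were 803, 1346 and 2199 (2, 4 and 6 h of ALLN) and 363, 577, 800 and 975 (tunicamycin) with a pseudocount of 0.1, and 174, 313, 628 and 831 (ALLN) and 64, 122, 205 and 289 (tunicamycin) with 5. At 1.5-fold they were 1638, 2696, 4245 and 4784 (ALLN) and 586, 1032, 1910 and 2002 (tunicamycin), and at 4-fold 96, 147, 224 and 313 (ALLN) and 57, 78, 99 and 113 (tunicamycin).

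Of the list calls by camera (9 for ALLN, 11 for tunicamycin, 18 for slopes, 17 for matched times), 0 held with an estimated correlation in each (limma, 3, 5, 5 and 1 at an unadjusted p under 0.05), while fry gave 7 for tunicamycin and 4 for matched times.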

Other observations

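The gene families below were chosen after the results were seen, by grouping symbols on their shared stem. Genes of the fixed lists, such as KRT14, COL1A1 and COL6A1, and joined symbols were left out, so a family is not the whole stem; 99 families of at least 10 members were tested with camera in limma. The families described are a choice among them.

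Symbols with the stem of keratins, the intermediate filaments of epithelia, stood higher in ALLN as a family. Of 17 members outside the fixed lists, 7 of them pseudogenes, 10 rose and 0 fell, 3 of the risers being pseudogenes, with a median of 0.69 (0.78 with quantile normalization; limma camera, adjusted p = 0.000533; adjusted p = 0.409 with an estimated correlation). KRT6A, a keratin of stressed and wound-edge epithelium, rose by 5.22 from 35.6 to 1360 FPKM, and KRT16, its usual partner, by 4.90 from 5.69 to 181 FPKM. Close copies among keratins can share reads. In tunicamycin KRT6A stood at -0.22, and the slopes of 12 of the 17, 4 of them pseudogenes, were higher in ALLN (limma camera, adjusted p = 0.000125; adjusted p = 0.478 with an estimated correlation). Of 11 symbols with the matrix metalloproteinase stem, 6 rose and 0 fell in ALLN (limma camera, adjusted p = 0.00844; adjusted p = 0.912 with an estimated correlation), MMP10 by 4.10 from 0.189 to 19.6 FPKM and MMP15 by 2.28 from 8.93 to 50 FPKM.

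Of 15 symbols with the collagen stem outside the fixed lists, which include COL4A3BP, not a collagen gene, 4 rose in ALLN (limma camera, adjusted p = 0.0319; adjusted p = 0.912 with an estimated correlation). COL6A2 rose by 1.96 from 4.10 to 21.2 FPKM and COL7A1, the anchoring fibril collagen of the epithelial basement membrane, by 1.28 from 14.7 to 37.7 FPKM, and 12 of the 15 had the higher slope in ALLN (limma camera, adjusted p = 0.000125; adjusted p = 0.607 with an estimated correlation). Part of that difference lies in tunicamycin, where the family median was -0.38 with 0 risers and 0 fallers (limma camera, adjusted p = 0.00858, and 0.995 with an estimated correlation). Of 11 SRSF splicing factor genes, 4 fell and 0 rose in ALLN, and the family did not pass (limma camera, adjusted p = 0.0508). In the slopes 6 were lower in ALLN (limma camera, adjusted p = 0.0478; adjusted p = 0.718 with an estimated correlation). SRSF6 fell by 1.62 from 85.2 to 33.9 FPKM, and SRSF2 fell by 1.19. Of 14 RAD genes, many of them of DNA repair, 7 fell and 0 rose in ALLN (limma camera, adjusted p = 0.00844; adjusted p = 0.912 with an estimated correlation). Symbols with the EIF stem of translation initiation factors, with 15 of 45 risers, and with the SH stem, with 8 of 27, also stood higher in ALLN, with 0 fallers in both (limma camera, adjusted p = 0.00844 and 0.0112; adjusted p = 0.912 and 0.409 with an estimated correlation). The EIF median of 0.38 was 0.19 with quantile normalization. In tunicamycin the EIF family was also called, with a median of 0.13 and 0 risers (limma camera, adjusted p = 0.0477, and 0.995 with an estimated correlation). Under median centring and quantile normalization the ALLN medians of these families kept their sign.

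By annotated class, 37 of 472 lncRNAs rose and 77 fell in ALLN, against 1565 and 1490 of 10698 protein-coding genes, and the difference between the classes was not tested. A further 2693 tested genes had no annotated class, of which 275 rose and 301 fell, so either class may be incomplete.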
